A study of Gallus gallus with 8 samples.

How the data were processed

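Messenger RNA was measured in 2 dissected tissues of the chick embryo at stage 8 of the Hamburger and Hamilton series, when the cranial neural folds rise on either side of the neural plate. The cranial neural fold, the raised edge that holds the future neural crest and dorsal neural tube, and the ventral part of the cranial neural plate, which lies over the midline, each gave 4 samples. Per the labels' protocols, eggs were kept at 38 °C, the pieces were cut with tungsten needles in ice-cold buffered saline, RNA was extracted with TRIzol, and biotin-labelled cRNA was made from 6 µg of total RNA. The series text gives 80 to 114 embryos with n = 4, so each sample appears to be a pool, but the labels do not say how embryos were divided among the samples. The p-values therefore measure the spread between these samples, part of which may be technical.

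Each sample was hybridised to 1 Affymetrix GeneChip chicken genome array. The deposited values are linear intensities, 1 per probe set and array, made with GCOS (Affymetrix's analysis software) per the submitters' processing notes. The version, the background treatment and the detection calls were not given in the sources used here. In the file, the mean intensity after trimming 2% of probe sets at each end was 500.1 on every array, which is what scaling of each array to a single target gives. The table held 38535 probe sets in 8 columns, and 0 columns of per-sample values were left unused.

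The intensities were analysed as log2(value + 16), so changes of dim genes are understated. The 96 probe sets whose names mark them as Affymetrix controls were left out. Array medians differed by 0.80 on this scale, over the limit of 0.5 set in the design, and by that rule the arrays were quantile normalized. This makes the planned quantile alternative identical to the analysis reported here, and the values as deposited were added as an alternative in its place. Probe sets whose mean over all 8 arrays lay at or above the 40th percentile were kept, which left 23063. Each was tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (statmod 1.5.0), neural fold against neural plate, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. All log2 changes are neural fold minus neural plate, with the model's SE. Folds are those of log2(value + 16) after normalization.

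A background limit was taken per array as the 95th percentile of 59 control probe sets for bacterial transcripts and artificial tags, carried onto the normalized scale. Between 59.8% and 73.9% of probe sets lay above it on an array. Where a gene lay at or below the limit on all 4 arrays of a tissue, its change is given as at least N-fold, from the brighter tissue's mean against the mean of, per array, the higher of the limit and the gene's own value. Where only some arrays of the dimmer tissue lay above it, the fitted change is given with their number. Genes with only a bound lie on the same side of the median of their list at this bound as at their fitted value.

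Symbols came from the platform's 2016 annotation, updated through Entrez gene IDs against a RefSeq table of assembly GRCg7b. Of the probe sets without control names, 27168 had 1 symbol, 177 had several and 11094 had none. The IDs of 26853 were found in the RefSeq table and 0 symbols changed. No genome was used and no coordinates are given, since the files name no build. For a gene with several probe sets, the one with the highest mean over all 8 arrays stood for it in gene lists, which left 10279 genes, while all probe sets were tested singly.

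Before the data were examined, the test, the filter, the normalization rule, 24 gene lists, the rule for named genes and most alternatives were fixed. The rule named the 12 genes with the largest rise and the 12 with the largest fall among probe sets past the threshold with 1 symbol and no overlap between the tissues. It also named up to 4 members of each list with the smallest adjusted p past the threshold, and a set of tissue identity genes whatever their result. It gave 57 genes. NKX2-2, one of the identity genes, had no tested probe set with 1 symbol and is not analysed here.

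The lists covered neural plate border regulators, neural crest specifiers, dorsal and roof plate signals, floor plate and ventral genes, hedgehog co-receptors, pan-neural genes, forebrain and midbrain genes, hindbrain and Hox genes, and epithelial to mesenchymal transition. They also covered non-neural ectoderm, head mesoderm, notochord and prechordal plate, endoderm, blood and endothelium, and the cell cycle. The remaining lists held the BMP, Wnt, FGF, Notch and retinoic acid pathways, guidance genes, stress genes, glycolysis and hypoxia, and ribosomal proteins. Each list was tested with limma's camera with a preset correlation of 0.01 between genes, which asks whether members shifted relative to the other genes, with adjustment over the 24 lists. Some genes stand in several lists, such as TFAP2A and TFAP2B (border and crest), SHH and FOXA2 (floor plate and notochord) and BMP4 (border, dorsal signals and BMP).

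The sample titles number the arrays 1 to 4 in each tissue, and nothing in the labels says whether equal numbers share a day or a set of embryos. Deviations from the tissue means correlated between the arrays of equal number at 0.62, 0.19, 0.29 and 0.21 over probe sets, and 6 of the 8 arrays correlated best with their own number. Every pair lay above the correlation of 0.1 set as the criterion, so by that rule the numbers were treated as pairing the arrays. The highest correlation with an array of another number was -0.24 for number 1. For numbers 2, 3 and 4 it was 0.28 each. Only number 1 stood clearly apart from unlike numbers, so a pairing of numbers 2 to 4 is not shown. The fit without the block stayed the main one, as fixed in the design, and the fit with the number as a block is given where it changed the call of a named gene, a list or a list member.

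The steps were tested on simulated data for this comparison with 23063 probe sets. Of 100 probe sets given a log2 change of 1, 28 were recovered, and of 100 given a change of 2, 64 were recovered, all with the right sign, while 10 unchanged probe sets were called. The list test called 1 of 1 raised lists of 20 genes and 0 of 50 lists without a shift. The simulated genes varied independently and the 50 lists were random. The test therefore cannot show how often lists of correlated genes are called wrongly at the preset correlation. The number of arrays and the spread between arrays of a tissue limit the precision, and changes near 2-fold were often missed. The simulation took that spread from the data, with the arrays numbered 1 included.

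Alternatives changed the pseudocount (1 and 64), the filter (none, or the 60th percentile), the normalization, the block, the variance prior, array weights, the threshold, the handling of several probe sets per gene and the list test, or left out each array in turn. After the data had been seen, the values as deposited, a fit without both arrays numbered 1 and a fit with a term for those arrays were added.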

Results

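The study set the cranial neural fold against the ventral cranial neural plate of the chick at stage 8, with 4 arrays each, to compare the transcriptome of the territory that holds the neural crest with that of the ventral neural plate. Arrays of 1 tissue correlated at 0.878 to 0.970 with each other. The arrays numbered 1 stood apart in both tissues. Their median intensities were 195.7 in neural fold and 182.1 in neural plate, against 105.3 to 121.6 on the other 6 arrays. The ratio of 3' to 5' signal of beta-actin, a measure of RNA integrity, was 1.77 ± 0.284 (SD, n = 4) in neural fold and 1.80 ± 0.188 in neural plate (exact two-sided permutation p = 0.857). That of GAPDH was 1.09 ± 0.216 and 0.995 ± 0.158 (exact two-sided permutation p = 0.486), where the smallest p this design allows is 0.0286.

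PAX7, TFAP2B, SNAI2 and MSX2, transcription factors of the neural plate border and neural crest, were among the genes with the largest rise in neural fold. NKX6-1, FOXA2 and SHH, which pattern the ventral neural tube, and CHRD, TBXT and GSC, known from the midline mesoderm and prechordal plate, were higher in neural plate. In all, 295 of 23063 probe sets passed the threshold, 160 higher and 135 lower in neural fold (54.2% higher). Of these, 140 were over 2-fold higher and 117 over 2-fold lower, and 24 and 15 were over 8-fold as fitted. With dim arrays at their background limits, 138 and 112 were over 2-fold and 21 and 9 over 8-fold. Of the 295, 17 lay above the limit on 0 arrays of the dimmer tissue and 68 on only some. They covered 206 named genes, 110 higher and 96 lower, with 0 genes called in both directions, and 49 probe sets without a single symbol. All 295 had no overlap between the tissues, as had 6.71% of all tested probe sets, where chance gives 2.86%. Of 167 further tested probe sets of the called genes, 157 (94.0%) changed in the same direction as the leading one.

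**Figure D1:**
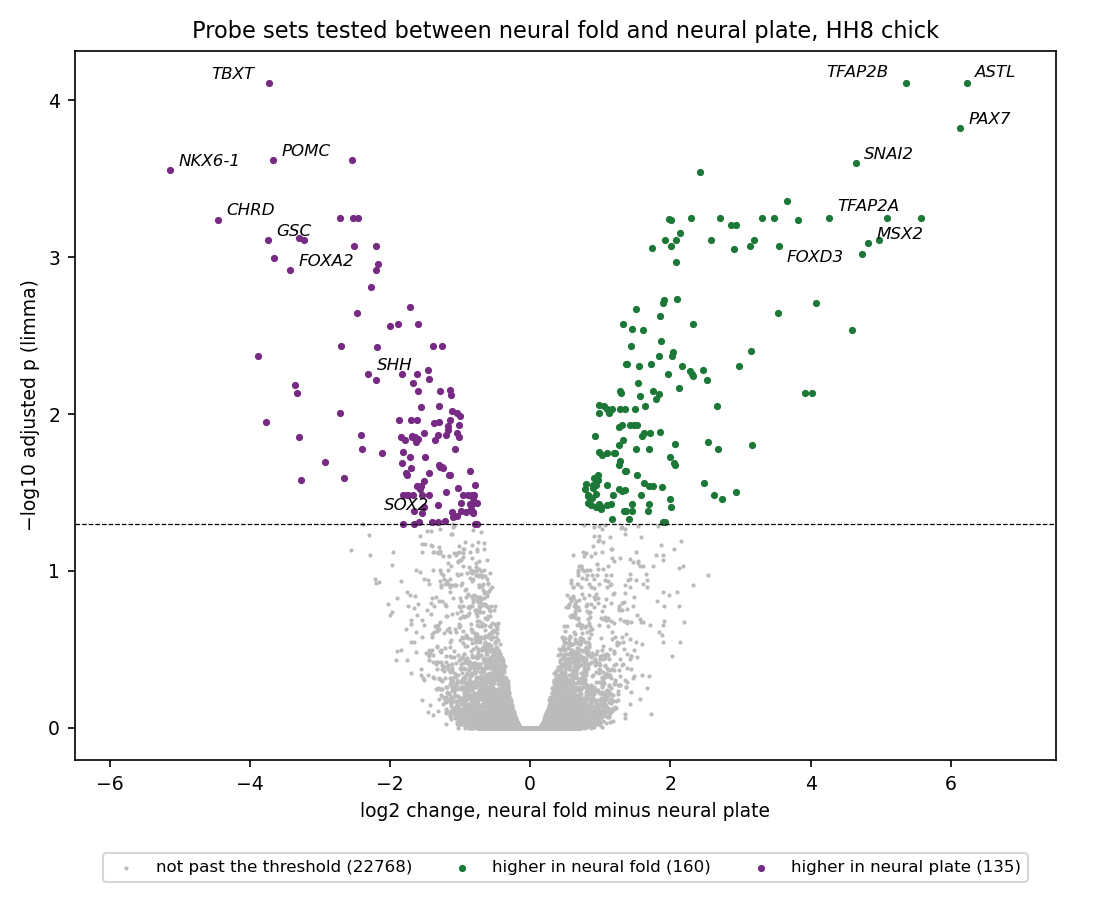
Log2 change between neural fold and neural plate (horizontal axis) against the negative log10 of limma's adjusted p (vertical axis), 1 point per tested probe set, with the threshold dashed. The 160 green points are higher in neural fold and the 135 purple points higher in neural plate, with ASTL at 6.23 and NKX6-1 at -5.13.

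Regulators of the neural plate border, the strip between neural plate and ectoderm, shifted towards neural fold as a list. PAX7 had a log2 change of 6.14 ± 0.31 (SE, limma adjusted p = 0.00015), with 11.81 ± 0.09 in neural fold and 5.68 ± 0.68 in neural plate (SD, n = 4). Only 1 of 4 neural plate arrays lay above the background limit, and with the others set at their limits PAX7 was 40.8-fold higher, against 70.3-fold as fitted. TFAP2B rose by 5.36 ± 0.24 (adjusted p = 7.7e-05), TFAP2A by 4.27 ± 0.30 and MSX2 by 4.82 ± 0.40. MSX1 rose by 2.86 ± 0.22 and DLX5, a homeobox gene of the border and ectoderm, by 3.82 ± 0.29. Of 17 measured members, 10 were higher, 0 lower and 7 not past the threshold, and 13 were higher when adjusted over the list alone (median change 1.89, camera adjusted p = 3.1e-26, and 0.00055 with an estimated correlation). DLX6 was at least 9.56-fold higher by 1 probe set (adjusted p = 0.00096), while its brighter probe set, which stood for it in the list, changed by 1.89 (adjusted p = 0.079). WNT1, a signal of the dorsal midline, differed by 0.01 ± 0.24 (adjusted p = 1.00), and lay near the background limit in both tissues. Leaving out both arrays numbered 1 gave 11 border members higher and 0 lower, and the number as a block added WNT3A (adjusted p = 0.016) and ZIC1 (0.028).

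Neural crest specifiers, the factors that set crest identity, also shifted towards neural fold. SNAI2 was 25.0-fold higher (4.65 ± 0.27, limma adjusted p = 0.00025), FOXD3 11.7-fold (3.54 ± 0.29) and SOX8 3.96-fold (1.99 ± 0.15). SOX9 rose by 1.37 ± 0.22 (adjusted p = 0.023). Of 22 members, 9 were higher, 0 lower and 13 not past the threshold (median 1.13, camera adjusted p = 1.0e-22, and 0.0046 with an estimated correlation). Adjusted over the list alone, 16 were higher and 2 lower. The pair with lower values was TWIST1 (-1.98 ± 0.53, adjusted p = 0.18 over all probe sets) and SNAI1 (-1.20 ± 0.33, adjusted p = 0.19), both known from mesenchyme. SOX10, a later crest factor, had a change of 1.61 ± 0.35 (adjusted p = 0.093). It was called higher without both arrays numbered 1 and with a term for them. Without both arrays numbered 1, 12 were higher and 1, SNAI1, was lower, and the blocked fit also called SNAI1 lower, with 10 members higher (ID4 added). A term for the arrays numbered 1 gave 16 higher and 2 lower.

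Some signals of the dorsal neural tube were also higher. BMP5, a BMP ligand, was 16.9-fold higher in neural fold (4.08 ± 0.40, limma adjusted p = 0.0020), and BMP4 was at least 4.36-fold higher (adjusted p = 0.0023), since all 4 neural plate arrays lay at or below the background limit. DRAXIN, a secreted guidance protein and Wnt antagonist, rose by 2.09 ± 0.17, and WNT6 by 1.88 ± 0.32 (adjusted p = 0.029). Of 13 dorsal and roof plate signals, 4 were higher, 0 lower and 9 not past the threshold (median 0.84, camera adjusted p = 8.6e-06, and 0.016 with an estimated correlation). When adjusted over the list alone, 8 were higher and 3 lower (WNT4 at -0.68, BMP7 at -0.55 and RSPO3 at -0.61), and 7 were higher and 0 lower without both arrays numbered 1. With the block WNT3A was also higher (adjusted p = 0.016). Of 22 BMP pathway genes, 4 were higher (BMP4, BMP5, the antagonist FST at 1.31 ± 0.18 and the inhibitory SMAD6), 1 was lower (the antagonist CHRD) and 17 were not past the threshold. This list had a camera adjusted p of 0.0015, but adjusted p = 0.063 with an estimated correlation. The count for BMP pathway genes adjusted over the list alone was 10 higher and 3 lower. SMAD6 (1.18 ± 0.20, adjusted p = 0.033) lost its call with the block (0.070), without both arrays numbered 1 (0.074) and with median centring (0.057).

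**Figure D2:**
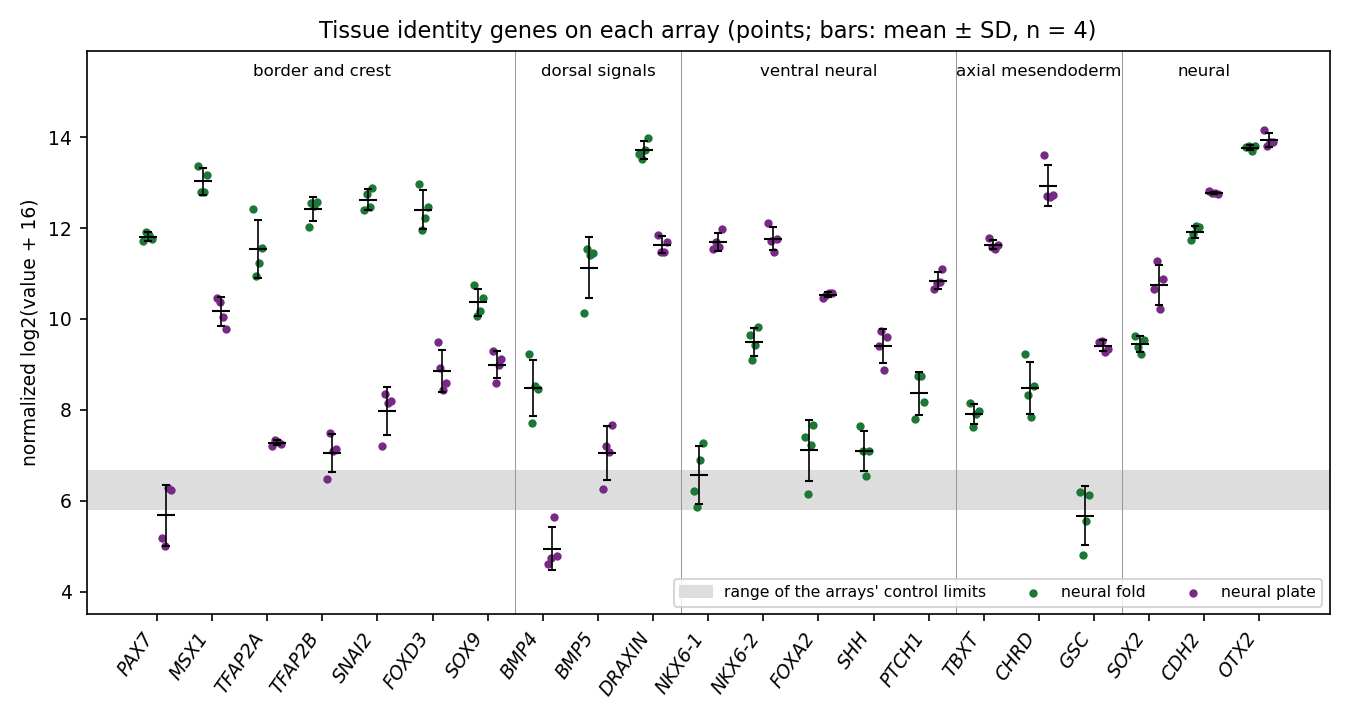
Normalized log2(value + 16) of tissue identity genes (vertical axis, log2 units) on each of the 4 neural fold arrays (green) and 4 neural plate arrays (purple), with mean ± SD as bars. The grey band spans the arrays' background limits, which PAX7 exceeded on 1 of 4 neural plate arrays and GSC on 0 of 4 neural fold arrays. OTX2 and WNT1 were not past the threshold, and only OTX2 of these is drawn.

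Genes of the floor plate and ventral neural tube shifted towards neural plate as a list. NKX6-1, a homeobox gene of ventral progenitors, had a log2 change of -5.13 ± 0.31 (35.1-fold, limma adjusted p = 0.00028), and its relative NKX6-2 one of -2.27 ± 0.21. FOXA2, a floor plate and midline factor, changed by -3.42 ± 0.31, and SHH, the ventralising signal, by -2.31 ± 0.27 (adjusted p = 0.0055). PTCH1, the hedgehog receptor and a target of the pathway, changed by -2.48 ± 0.25. Of 15 members, 0 were higher, 6 lower and 9 not past the threshold, and 7 were lower when adjusted over the list alone (median -1.21, camera adjusted p = 2.0e-11, and 0.0046 with an estimated correlation). The fit without both arrays numbered 1 gave 7 lower and 0 higher. With the block HHIP, a hedgehog-binding inhibitor and one of the 6, lost its call (adjusted p = 0.060) and OLIG2 was called lower (0.049). In contrast, CDON, a hedgehog co-receptor, rose in neural fold by 1.71 ± 0.24 (adjusted p = 0.013). It was the only 1 of 6 co-receptors and mediators past the threshold, over all probe sets and adjusted over the list alone, and that list did not shift (camera adjusted p = 0.17). Its median of -0.0059 and its test direction differed in sign.

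Genes of the notochord and prechordal plate, the tissue beneath the midline, shifted towards neural plate beside the ventral neural genes. TBXT, the mesoderm factor brachyury, changed by -3.72 ± 0.16 (13.2-fold, limma adjusted p = 7.7e-05), with 11.63 ± 0.11 in neural plate and 7.91 ± 0.22 in neural fold (SD, n = 4). CHRD, a BMP antagonist, changed by -4.45 ± 0.33, and GSC, a prechordal plate factor, was at least 7.11-fold higher in neural plate (adjusted p = 0.00078). Of 9 members, 0 were higher, 5 lower (with SHH and FOXA2, which neural tissue also expresses) and 4 not past the threshold, while 6 were lower adjusted over the list alone (median -2.31, camera adjusted p = 1.1e-13, and 0.0046 with an estimated correlation). NOG (-0.69 ± 0.26), NOTO (-0.37 ± 0.16), COL9A1 and COL2A1 (0.10 ± 0.41) were not past the threshold. The same number, 5, were lower without both arrays numbered 1.

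Markers of other germ layers gave few calls. SOX17, an endoderm factor, was lower in neural fold (-2.70 ± 0.29, limma adjusted p = 0.0037), the only 1 of 11 endoderm members past the threshold. APOA1 was also lower with the block (adjusted p = 0.012), and its dimmer probe set was lower without it (-1.99 ± 0.21, adjusted p = 0.0027). Adjusted over the list alone, 1 endoderm member was higher and 2 lower, and the list did not shift (camera adjusted p = 0.66, with a median of 0.04 and a test direction of opposite sign). The brightest TF probe set, which stood for transferrin in that list, changed by 0.04, while a pair of other TF probe sets changed by -2.52 and -2.45 (both adjusted p = 0.00056). Of 13 head mesoderm genes and 8 blood and endothelial genes, 0 passed in either direction (camera adjusted p = 0.16 and 0.46). The head mesoderm list was past the threshold, towards neural plate, without neural fold array 1 (0.048) or without neural plate array 4 (0.045), and ranged up to 0.42 without another array. Adjusted over the list alone, 0 head mesoderm genes and 1 blood gene, LMO2 (-2.39 ± 0.46, adjusted p = 0.0504 over all probe sets), were lower, and LMO2 passed in the blocked fit (0.0062).

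Of 16 pan-neural genes, 0 were higher, 2 lower and 14 not past the threshold, and 6 were lower adjusted over the list alone. The list had a median of -0.31 and a camera adjusted p of 0.00036, but adjusted p = 0.055 with an estimated correlation. SOX2, a neural progenitor factor, changed by -1.31 ± 0.24 (limma adjusted p = 0.038), and CDH2, the neural cadherin, by -0.86 ± 0.14 (adjusted p = 0.023, and not past the threshold with the values as deposited). SOX2 lost its call without both arrays numbered 1 (limma adjusted p = 0.071), where 3 members were lower (CDH2, MSI1 and SOX1). A term for these arrays gave 5 members lower, SOX2 among them, while 0 members passed with median centring. OTX2, a forebrain and midbrain factor, lay at 13.77 ± 0.05 in neural fold and 13.94 ± 0.16 in neural plate (n = 4), a change of -0.17 ± 0.14 (adjusted p = 0.98). Among 14 forebrain and midbrain genes and 7 hindbrain and Hox genes, 0 passed in either direction (camera adjusted p = 0.82 and 0.40). Adjusted over the list alone, 1 forebrain or midbrain gene was higher and 3 were lower, and 0 hindbrain genes passed. PAX2 was called lower with the block (adjusted p = 0.043).

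Cell adhesion and matrix genes moved singly rather than as a list. FN1, the matrix protein fibronectin, rose in neural fold by 1.73 ± 0.15 (limma adjusted p = 0.00088). Its 6 other probe sets changed by 1.44 to 2.01, and 5 of them were past the threshold. ADAM12, a metalloprotease, rose by 2.67 ± 0.35, CDH6, a cadherin of the dorsal neural tube, by 1.53 ± 0.25, and CLDN1, a tight junction protein, by 0.97 ± 0.16. These were the 4 of 31 members of the epithelial to mesenchymal transition list past the threshold, with 0 lower (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.66). The median of -0.13 differed in sign from the test's direction. CDH6 lost its call with the number as a block (adjusted p = 0.070). CDH1, the epithelial cadherin, rose by 2.30 ± 0.16 (adjusted p = 0.00056), the only 1 of 14 ectoderm and placode genes past the threshold, with 0 lower and 4 higher and 1 lower adjusted over the list alone. That list had a camera adjusted p of 0.014, which became adjusted p = 0.17 with an estimated correlation and 0.083 with the block. It was also lost without neural fold array 1 (0.23), without neural plate array 3 (0.093), and without both arrays numbered 1 (0.067).

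Among guidance genes, NRP2, a semaphorin receptor, rose in neural fold by 2.02 ± 0.23 (limma adjusted p = 0.0042) and EPHA7 by 1.84 ± 0.21, while EPHA3 changed by -1.45 ± 0.25 (adjusted p = 0.033, 0.068 with the block and 0.055 without both arrays numbered 1). Of 40 members, 2 were higher, 1 lower and 37 not past the threshold, against 10 higher and 6 lower adjusted over the list alone, and the list was not past the threshold (camera adjusted p = 0.052, 0.11 with an estimated correlation and 0.15 with median centring). It passed, towards neural fold, with the filter at the 60th percentile (8.0e-05), a pseudocount of 64 (0.048), an intensity trend (0.030), the mean of a gene's probe sets (0.030), without neural fold array 4 (0.048) and without neural plate array 2 (0.039). Without both arrays numbered 1, 7 were higher and 1 lower, and the block gave the same counts, with EPHA4, PLXNA2, ROBO2, SEMA3D and UNC5B added as higher and SEMA6A as lower.

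Of 35 Wnt pathway genes, 2 were higher, 2 lower and 31 not past the threshold. The antagonist WIF1 was at least 2.85-fold higher in neural plate (limma adjusted p = 0.020, and 0.091 with the block), and the antagonist SFRP1 changed by -1.22 ± 0.23 (adjusted p = 0.048). NKD1, an inhibitor of the pathway, rose by 1.10 ± 0.18 (adjusted p = 0.029, and 0.079 with the block), as did WNT6. FGF3 and FGF19 were lower in neural fold, by -1.26 ± 0.14 and -0.82 ± 0.14 (the latter 0.058 with the block), and were the only 2 of 18 FGF pathway genes past the threshold. The Notch ligand DLL1 rose by 0.94 ± 0.16 (adjusted p = 0.032, and 0.057 with the block), 1 of 13 pathway genes. CYP26A1, which breaks down retinoic acid, rose by 1.68 ± 0.31 (adjusted p = 0.041), 1 of 13. None of these 4 lists shifted (camera adjusted p = 0.55, 0.51, 0.82 and 0.21), and in the retinoic acid list the median of -0.02 and the test's direction differed in sign. The block added WNT3A (adjusted p = 0.016), the FGF target DUSP6 (0.031) and DHRS3 (0.026) as higher and STRA6 (0.022) as lower. Adjusted over the list alone, 5 Wnt genes were higher and 5 lower, 2 FGF genes higher and 2 lower, 1 Notch gene higher, and 4 retinoic acid genes higher and 2 lower.

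Genes of glycolysis and the hypoxia response lay lower in neural fold as a list. LDHA, lactate dehydrogenase A, changed by -2.39 ± 0.36 (5.26-fold, limma adjusted p = 0.017) and was the only 1 of 20 members past the threshold, with 0 higher. VEGFA had a change of -1.27 ± 0.41 and P4HA1, a collagen prolyl hydroxylase subunit, one of -0.83 ± 0.18 (adjusted p = 0.082), neither past it. P4HA1 was called lower with the number as a block (0.034), without both arrays numbered 1 (0.018) and with a term for them (0.0035). Only 2 members had a change above 0, and 2 were lower adjusted over the list alone (median -0.29, camera adjusted p = 2.9e-06, and 0.0077 with an estimated correlation). LDHA lost its call with median centring, and the list did not. Without both arrays numbered 1, 3 members were lower.

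BTG2, an antiproliferative early response gene, rose in neural fold by 1.79 ± 0.23 (limma adjusted p = 0.0080), 1 of 15 stress genes past the threshold (2 higher adjusted over the list alone). The stress list had a camera adjusted p of 0.013, but adjusted p = 0.063 with an estimated correlation, and it was lost without neural plate array 1 (0.10), without neural fold array 3 (0.052), without both arrays numbered 1 (0.055), and with no filter on dim probe sets (0.092). Among 26 cell cycle genes and 58 ribosomal protein genes, 0 passed in either direction, also adjusted over the list alone (camera adjusted p = 0.66 and 0.82). The ribosomal list shifted towards neural fold, by a median of 0.08, with the values as deposited (0.0091) and by 0.11 with median centring (0.014). The direction of the cell cycle list changed under the same scalings.

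**Figure D3:**
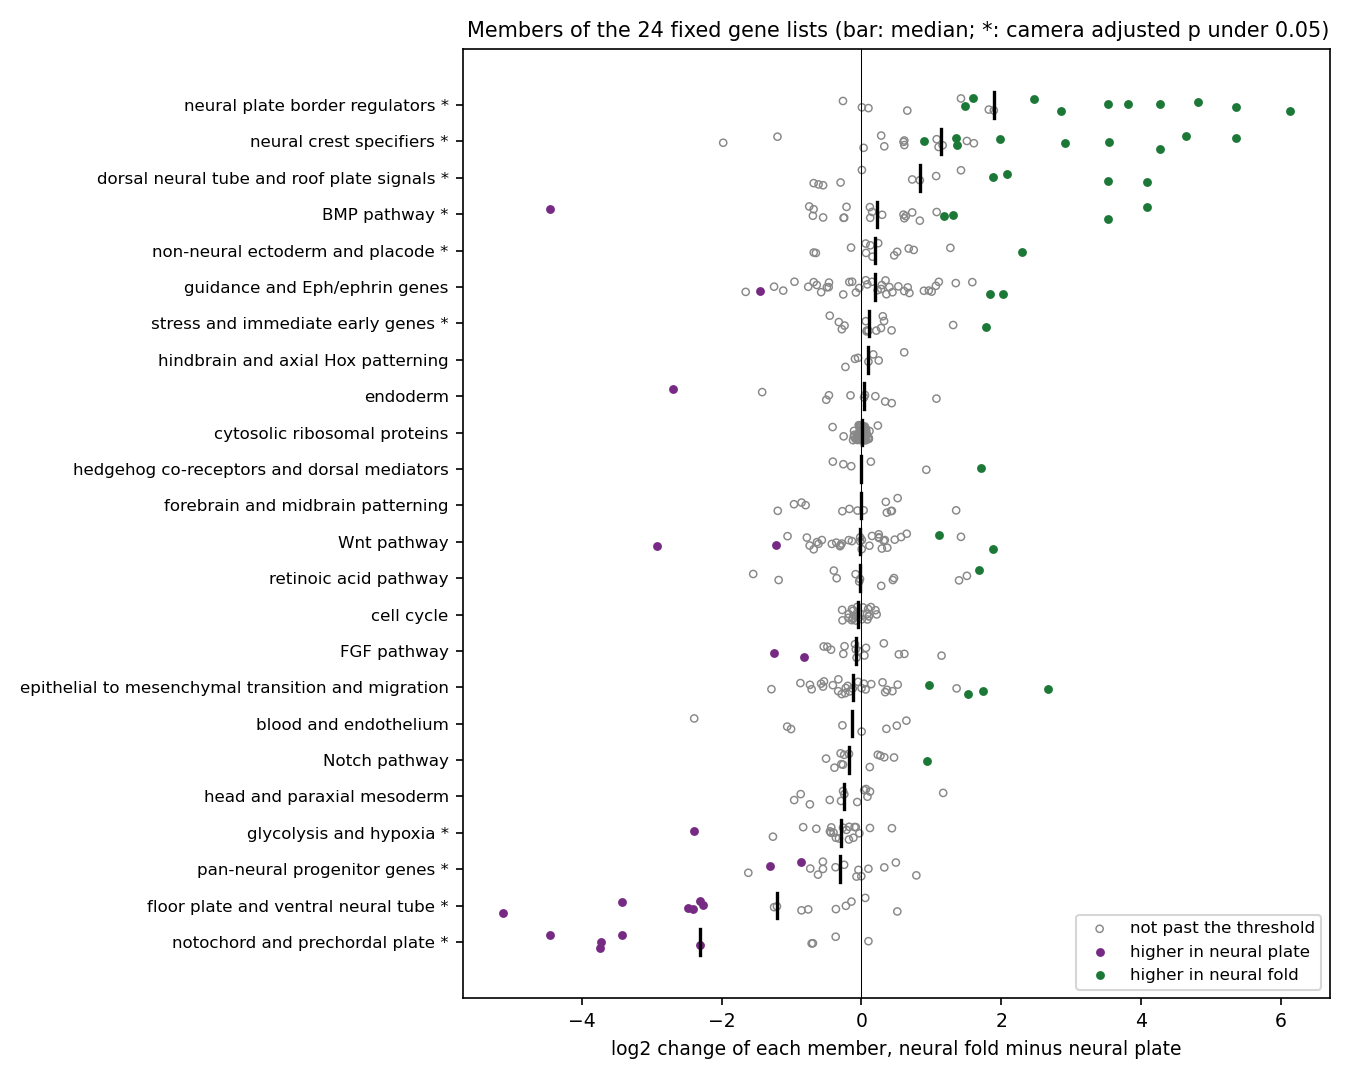
Log2 change of every measured member of the 24 lists (horizontal axis, neural fold minus neural plate), 1 row per list, with the median as a bar. Filled points passed the threshold, and asterisks mark the 10 lists with a camera adjusted p under 0.05, of which 6 held with an estimated correlation.

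In all, 10 of 24 lists shifted, 6 higher and 4 lower in neural fold. With an estimated correlation 6 held, namely border, crest, dorsal signals, floor plate, notochord, and glycolysis and hypoxia. By fry, 13 lists moved on balance in 1 direction, with the guidance, hedgehog co-receptor and retinoic acid lists added to the 10, and 21 held genes that changed in either direction. These tests do not compare a list with other genes.

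Several of the largest changes lay outside the lists. ASTL, an astacin-family metalloprotease, was 74.9-fold higher in neural fold (6.23 ± 0.27, limma adjusted p = 7.7e-05). NOXO1, which organises an NADPH oxidase, rose by 4.59 ± 0.48, and the chemokine CXCL14 by 3.66 ± 0.24. Higher in neural plate were POMC, the precursor of melanocortin peptides (-3.66 ± 0.21, adjusted p = 0.00024), and the matrix protein POSTN (-3.88 ± 0.43). The protease inhibitor TIMP3 changed by -3.29 ± 0.26. LEFTY1, a Nodal antagonist, changed by -3.33 ± 0.42 and the neurexin ligand NXPH1 by -3.35 ± 0.41, but each lay above the background limit on only 1 of 4 neural fold arrays. With the others at their limits the folds of LEFTY1 and NXPH1 were 5.21 and 5.38, against 10.1 and 10.2 as fitted. EMILIN3, a matrix protein, changed by -3.76 ± 0.52 and FRMD5 was at least 5.05-fold higher in neural plate (adjusted p = 0.0010), but each had a second probe set that differed by only -0.07 and -0.12.

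Of the called named genes, 19 lay above the background limit on only some arrays of the dimmer tissue, so their changes rest partly on values at background. It was 1 of 4 arrays for CDH6, EMILIN3, LEFTY1, MSX2, NXPH1, PAX7 and SOX17, 2 of 4 for ADAM12, ASTL, NKX6-1 and NOXO1, and 3 of 4 for BMP5, CXCL14, EPHA3, FOXA2, POSTN, SHH, TFAP2B and WNT6. With dim arrays at their limits the fold was 65.7 for ASTL, 29.1 for NKX6-1 and 15.8 for BMP5, while EMILIN3 went from 13.6 to 7.196 and NOXO1 from 24.1 to 14.6.

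The arrays numbered 1 form 1 pair. Among genes above the background limit on all 8 arrays, SNAI2 differed by 5.20 in that pair and by 4.46 in the others, TFAP2A by 5.22 and 3.95, FOXD3 by 3.49 and 3.56, TBXT by -3.63 and -3.75, and SOX2 by -1.03 and -1.41. NKD1, also above the limit on all 8 arrays, differed by 1.71 and 0.90. WIF1 and CDH6, which lay near or below the limit in the dimmer tissue, differed by -0.94 against -3.59 and by 0.65 against 1.82. Without both arrays numbered 1, 540 probe sets passed (257 higher, 283 lower), 265 of them among the 295. With a term for these arrays 863 passed (386 higher, 477 lower), including all 295. With the number as a block 398 passed (197 higher, 201 lower), 245 of them shared.

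Some calls were lost when 1 array was left out, among them those of large changes such as EMILIN3, WIF1 and LDHA. Apart from EMILIN3 and FST, each was lost without each of several arrays, so no single array carried it. The changes kept their sign, with FGF19 between -0.87 and -0.75 and LDHA between -2.64 and -2.09. Without neural fold array 2, 3 or 4 the count was 158, 159 or 153, and without neural plate array 2, 3 or 4 it was 183, 166 or 139. Without array 1 it was 292 (neural fold) or 301 (neural plate). CDH2, SOX9, CDH6 and WIF1 each lost their call without any 1 of the 6 arrays numbered 2 to 4, with highest adjusted p of 0.097, 0.096, 0.097 and 0.082. CLDN1, DLL1 and CYP26A1 did so also without neural fold array 1 (highest 0.11, 0.13 and 0.15), and NKD1 and SFRP1 also without neural plate array 1 (highest 0.098 and 0.17). FGF19 lost it without any 1 array (highest 0.14), SOX2 and EPHA3 without any but neural plate array 3 (0.14 and 0.12), and WNT6 without any but neural fold array 2 or neural plate array 1 (0.11). LDHA lost it without neural fold array 3 or 4 or neural plate array 2, 3 or 4 (highest 0.072). CDON lost it without neural fold array 3 or 4 or neural plate array 2 or 3 (highest 0.056), and EMILIN3 and FST without neural plate array 4 (0.051 and 0.058).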

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

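The TBXT test of carried tissue and the tests on low oxygen and labelled RNA were chosen after the values they use had been seen. So was the error given with the slopes of the array pairs. The other tests, among them that on carried tissue in a single pool, were planned before their results. In 13 of 122 groups of 4 arrays, 1 array lay far from the other 3, measured by its gap against the range of the group. Chance alone gives this in about 1 in 20 groups. In 11 of the 13 the array was numbered 1. In neural fold array 1, the median intensity was 195.7 against 106.2 to 109.9 on the others. The same array had lower normalized log2 values of BMP5 (10.13), EPHA7 (10.34), LDHA (9.63), MSX2 (9.66) and TFAP2B (12.01) than the other 3, and higher values of CYP26A1 (12.94), FST (12.56) and SFRP1 (11.19). Neural plate array 1 stood out with a high CHRD value (13.61 against 12.69 to 12.72) and a low SNAI2 value (7.202 against 8.16 to 8.35). The exceptions were neural fold array 3 for CDH1 (10.36 against 9.995 to 10.02) and OTX2 (13.69 against 13.79 to 13.80).

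The arrays numbered 1 therefore differ from the rest in both tissues. The hybridisation controls, which are spiked in at fixed amounts and scaled with the array, were brighter on array 1 than on every other array of its tissue, by 0.128 log2 units in neural fold and 0.848 in neural plate. This is consistent with less labelled sample RNA on those arrays, but the neural fold difference is smaller than the SD of 0.21 among its other 3 arrays. The number 1 pair followed the other pairs with a slope of 0.944 ± 0.019 (SE over probe sets, which are not independent). The pairs numbered 2 to 4, taken the same way, gave 0.978, 0.941 and 0.941. By the rule set beforehand, a slope within the range of the others speaks against compressed tissue differences on the arrays numbered 1. Its gap to the lowest other slope was smaller than the error, so compression was not decided. The slopes rest on 540 probe sets for number 1, but on 65, 69 and 59 for the others. A different day or set of embryos remains open, since the labels give neither, and no biological explanation was tested.

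The count of 295 changed probe sets was set against every split of the 8 arrays into 4 and 4. Of the 35 splits, 1 gave as many, the real one, and the highest other gave 2. This is the smallest share that 35 splits allow. It counts against a chance division only where all 8 arrays are exchangeable, which may not hold, since the arrays numbered 1 differ from the rest. With the numbers as pairs, only the 8 splits that part all 4 numbers compare with the real one, too few for a share under 0.05 (the smallest is 0.125), and the highest other of these gave 0.

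Genes of the axial mesendoderm were higher in neural plate. The shift did not rest on a single neural plate pool. The notochord and prechordal plate list stayed lower in neural fold without any 1 neural plate array (highest camera adjusted p = 2.0e-09). Whether a single pool held a larger share of carried tissue is not decided by this, since the list could pass with unequal shares. Tissue beneath the plate carried in every pool cannot be told apart from expression within the dissected plate, and a tissue difference in the plate itself stays open. TBXT lay at least 4.93 log2 units above the background limit on every neural plate array, but TBXT was itself one of the called genes, so this value decides nothing. Other markers do not decide it either. SOX17 (-2.70, limma adjusted p = 0.0037), a pair of TF probe sets (-2.52 and -2.45) and the dimmer APOA1 probe set were lower in neural fold. So were the brighter APOA1 probe set and LMO2 with the block (0.012 and 0.0062). The head mesoderm list was lower without neural fold array 1 (camera adjusted p = 0.048) or neural plate array 4 (0.045). In contrast, COL2A1, NOTO and the brightest TF probe set, at 0.10, -0.37 and 0.04, and the endoderm list (0.66) were not past the threshold.

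The glycolysis and hypoxia list was lower in neural fold with only LDHA past the threshold. LDHA alone does not account for the shift, since the list without it had a camera p of 7.4e-06, and 0.0028 with an estimated correlation. Whether low oxygen or delay while the neural plate pieces were dissected contributed is not decided. The 8 oxygen-regulated members had a median change of -0.44 with 7 below 0 (camera p = 4.2e-05, and 0.037 with an estimated correlation). These members are part of the list that showed the shift, so a fall among them was likely whatever its cause. A metabolic difference between the tissues would give the same values and was not tested.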

How the results depend on the processing

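The values as deposited, the fit without both arrays numbered 1 and the fit with a term for those arrays were chosen after seeing the data, and the other alternatives were planned. No named gene or list reversed direction where it was called. The balance of changed probe sets did reverse. In the reported fit 160 were higher and 135 lower in neural fold. More were lower than higher with array weights, with the replicate block, without both arrays numbered 1 and with a term for them. Under the other alternatives that gave such counts more were higher. The share of 54.2% had a lower 95% bound of 48.4%, so a majority in either direction is not shown. The count of 295 stayed between 205 and 398 under both other pseudocounts, both filters, median centring, the values as deposited, both variance priors, 1 probe set per gene and the replicate block. It was 872 (46.0% higher in neural fold) with array weights, 540 (47.6%) without both arrays numbered 1 and 863 (44.7%) with a term for them. A term for the arrays numbered 1 leaves each fitted change as it was, since each tissue has 1 of them. The 863 therefore reflects different error estimates alone. The cause of the larger counts with array weights and without both arrays numbered 1 was not tested. At an adjusted p under 0.01 it was 129, 83 higher and 46 lower. Leaving out 1 array at a time gave 139 to 301 probe sets, 53.2% to 64.7% higher, 9 to 11 shifted lists and 39 to 50 named genes past the threshold, with fewer samples in each fit. The number of shifted lists was 6 with an estimated correlation and 21 by fry's mixed test, which counts changes in either direction, and between 8 and 13 otherwise. The robust prior gives no list result, since camera does not use it. The border, crest, floor plate and notochord lists stayed past the threshold in every list test run. Without 1 array their medians ranged from 1.66 to 2.18, 1.02 to 1.26, -1.40 to -0.76 and -2.49 to -2.13.

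With the replicate block, 398 probe sets passed (49.5% higher), 9 lists shifted and 49 named genes were past the threshold. CDH6, DLL1, EPHA3, FGF19, NKD1, WIF1 and the ectoderm list lost their call, and the pairing changed no other call of a list or of a gene named by the rule. Among other list members it ended the calls of SMAD6 and HHIP and added 18, among them P4HA1, OLIG2 and 6 guidance genes. Of 55 called named genes, 38 stayed past the threshold under every alternative that tested them, among them PAX7, SNAI2, FOXD3, NKX6-1, SHH and TBXT, and 17 lost it under at least 1. With no filter on dim probe sets, where more are tested, 12 lost it, as did the stress list (0.092). The guidance list, at 0.052 and not called in the reported fit, was called by camera under 4 other settings and without either of 2 arrays, and the head mesoderm list without either of 2 arrays. A pseudocount of 1 ended the calls of CYP26A1, EMILIN3 and SFRP1, the robust prior that of SFRP1, the intensity trend that of CDH6, and the mean of a gene's probe sets those of CDH2 and DLL1. Median centring ended the calls of CDH2, CDH6, FGF19, LDHA and SOX2, and the values as deposited those of CDH2, CDH6, DLL1 and WNT6. Signal over background limits the lowest values: BMP4, DLX6, GSC, FRMD5 and WIF1 have only bounds, and 19 other called named genes lay above it on only some arrays of the dimmer tissue.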

Other observations

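The genes in this part were chosen after their values were seen, by the rule given with each. Outside the fixed lists, 5 genes had at least 3 probe sets past the threshold, all in 1 direction per gene. ENC1, an actin-binding protein of the kelch family, was higher in neural fold by 1.91 to 2.71 log2 units in 3 of 4 tested probe sets (limma adjusted p from 0.00056 to 0.0019). ELL2, a transcription elongation factor, was higher by 1.604 to 2.53 in 3 of 3, the transcription factor ZFHX4 by 1.27 to 2.09 in 3 of 4, and the phosphatase PPM1E by 1.20 to 1.37 in 3 of 4. PCSK5, a proprotein convertase that processes secreted proteins, was lower in neural fold by -1.67 to -1.30 in 4 of 6. All called probe sets of these 5 genes also passed without both arrays numbered 1. With the number as a block, 3 of the 4 PCSK5 and 2 of the 3 ZFHX4 probe sets passed. Leaving out 1 array left at least 3 for ENC1 and ELL2, 2 for PCSK5, and 1 for ZFHX4 and PPM1E.

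A further 15 genes outside the lists had 2 probe sets past the threshold, and in 6 of them both had an adjusted p under 0.01. Of these 6, the lipid phosphatase PLPP1 was higher in neural fold by 2.43 and 2.58 (largest adjusted p = 0.00078), the phosphatase DUSP5, which acts on ERK, by 2.32 and 2.98 (0.0049), and PDLIM4, a PDZ and LIM domain protein, by 1.32 and 1.57 (0.0076, in 2 of 3). Lower in neural fold were the matrix protein POSTN, by -3.88 and -2.72 (0.0042), SST1, annotated under that symbol, by -3.23 and -2.55 (0.00078, in 2 of 3 tested probe sets), and FGFRL1, an FGF receptor without a kinase domain, by -2.72 and -2.52 (0.0099). Both probe sets of each of these 6 genes also passed without both arrays numbered 1, with the block and without any 1 array.

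Of the 49 changed probe sets without a single symbol, 23 were higher and 26 lower in neural fold. The pair with the largest rise, unnamed here, was higher in neural fold by 5.58 ± 0.39 and 5.09 ± 0.37 (limma adjusted p = 0.00056 for both). Both lay above the background limit on 4 of 4 neural fold arrays and on 1 of 4 neural plate arrays. The largest fall among them was -3.30 ± 0.48 (adjusted p = 0.014).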
